A study of Drosophila melanogaster with 2 samples.

How the data were processed

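Small RNAs from Drosophila melanogaster ovaries were compared between 1 library of cuff heterozygotes and 1 library of cuff mutants. Per the labels, the heterozygote RNA came from a mixture of ovaries of the genotypes cuff[wm25]/CyO and cuff[qq37]/CyO, the mutant RNA came from cuff[wm25]/cuff[qq37] ovaries, and flies were 3 to 10 days old. Per the labels' protocols, RNA was isolated with Ribozol and small RNAs of 19 to 29 nt were cloned. The submitters' processing notes name CASAVA 1.7 and the genome build dm3. The aligner, the mismatch rule, the rule for choosing 1 place for a sequence with several, and the sources of the annotation are not given in the sources used here.

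The authors deposited read counts: each line holds 1 distinct sequence, its genome position, its annotation and its count, with no normalization. Sequences of 15 to 42 nt were present. In every line the span of the position equalled the sequence length, and overlapping sequences never contradicted each other in a base. The libraries shared 95941 sequences, and all of them had the same place and annotation in both. Of miRNA reads, 1001685 lay on the strand of the annotated gene and 5 on the other. A start above the stop was therefore read as the minus strand.

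Annotations were sorted into miRNA, rRNA, tRNA, snRNA, snoRNA, signal recognition particle and RNase P RNA, transposon, satellite and other repeats, hairpin siRNA, Su(Ste), mitochondrial genome, gene, unannotated and other named entries. Gene names, biotypes and gene strands came from the RefSeq gene table and the Ensembl annotation of a later assembly, from which no coordinate was taken. Of 10701 CG or CR identifiers, 10391 matched. The piRNA-size set held reads of 23 to 29 nt annotated as transposon, satellite, gene or Su(Ste), or without annotation. Hairpin siRNA, mitochondrial and other named entries were left out of it, which goes beyond the exclusions set at the start.

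The main scale was reads per 1000000 miRNA reads of 20 to 24 nt. The dual-strand clusters, with dm3 intervals taken from general knowledge of the field, were 42AB (2R 2144349 to 2386719), 38C-1 (2L 20104255 to 20116383), 38C-2 (2L 20148259 to 20227581) and 80F (3L 23280548 to 23311746). The intervals of 38C-1 and 80F are the least certain. The uni-strand clusters were 20A (X 21392175 to 21431907) and flamenco (X 21502918 to 21684449). The design called for uniquely mapping reads and for antisense reads on transposons. The counts give 1 place per sequence and no orientation of a transposon, so cluster values use the deposited place and family values use both strands together. As a partial substitute for unique mapping, sequences found at 1 place in the 7206586 genome positions covered by any deposited sequence were also analysed. Copies of a sequence in uncovered positions escape this filter.

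Transposon families needed at least 1000 reads over both libraries, and a family counted as lower at a fold of 0.5 or less and as higher at 2 or more. The germline, intermediate and soma lists were fixed before the data were examined, and TART-C, Juan, 1360 and springer were not named by the annotation and not analysed here. List medians were placed among 10000 random lists of the same size matched on abundance in 5 bins. Ping-pong shares are the percent of 10-nt overlaps among opposite-strand 5′ overlaps of 1 to 23 nt. Genic piRNAs were sense reads on protein-coding genes outside the clusters, ranked by the sum of the scaled values. Exons and introns were not told apart, and the reads were not restricted to unique sequences.

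With 1 library per genotype no test across samples was possible, so no p-value and no SD between samples is given. Brackets hold 95% intervals, exact (Clopper-Pearson) for shares, exact Poisson for counts and exact conditional binomial for ratios. For the difference of list medians and the median fold over genes they hold the central 95% of 1000 Poisson resamples of the counts. Alternatives of the ping-pong share were set against 2 SD of 20 such resamples, and those of the U share against a normal 95% interval of the difference. All of these cover counting error only, since PCR copies are not independent molecules. The limit given for a count of 0 is always 3 counts of the total, or 7.08 and 5.02 reads per 1000000 miRNA reads in the heterozygote and the mutant library.

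The text names items by a rule set before the data were examined. It takes the fixed clusters, the 5 lowest and 5 highest folds of each transposon list, the 8 lowest and 8 highest of all families and of miRNAs with at least 1000 reads, the 10 most abundant miRNAs, the miRNA cell type markers, tj, brat, Ras85D, pcm, jing, the 10 genes with most sense reads, the hairpin loci, and the 5-kb windows outside the clusters with the 10 largest losses and 5 largest gains. The Su(Ste) repeats counted among the fixed clusters. Values of the telomeric elements of the germline list are given beyond this rule. The mir-309 cluster, the testis-enriched miRNAs and the mRNA marker lists were added after values were seen. So were the mitochondrial reads, a subtelomeric entry, reads placed on Y heterochromatin and white.

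The interval and fold calculation was checked on simulated data for the comparison of the mutant with the heterozygote library. Of 2041 simulated windows, 200 were changed 4-fold. Of the changed windows 99.5% were called, and of the unchanged ones 0.489%. Intervals held the true fold in 95.6% of windows. The simulated counts were Poisson draws with known totals, the model behind the intervals, without PCR copies or variation between libraries. These rates therefore check the calculation only and are not error rates of the real libraries. A simulated ping-pong share of 30.1% was recovered as 30.0%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The alternatives tried were other scalings, length windows, read minimums, sequence filters and counting of distinct sequences.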

Results

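Small RNAs were sequenced from ovaries of flies heterozygous or mutant for cuff, to see which small RNAs depend on it. The cuff gene encodes Cutoff, which acts with Rhino and Deadlock at the dual-strand piRNA clusters of germ cells. There was 1 library per genotype and no replicate, so every comparison below is between 2 libraries and has no replicate check. The heterozygote library held 2662668 reads of 744865 distinct sequences and the mutant library 6930241 reads of 431052. Only 2 reads in the heterozygote and 1 in the mutant lay in sense on cuff, so its small RNAs do not check the labels.

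The classes of RNA differed strongly between the libraries. Transposon sequences made up 46.5% of reads in the heterozygote library (46.4 to 46.5) and 4.35% in the mutant library (4.33 to 4.36). Ribosomal RNA made up 21.9% and 62.9%, and tRNA 1.88% and 15.3%. Per miRNA read, tRNA fragments were 15.03-fold, snoRNA fragments 14.8-fold and snRNA fragments 17.4-fold higher in the mutant library. The miRNAs made up 17.1% of the heterozygote and 9.38% of the mutant reads.

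Reads of piRNA size, 23 to 29 nt, were far scarcer in the mutant library. It held 0.533 of them per miRNA read against 2.92 in the heterozygote library, a ratio of 0.183 (0.182 to 0.184). As a share of all deposited reads the ratio was 0.0992. Satellites and other repeats were 110.0-fold lower per miRNA read, over all lengths. The commonest length of transposon reads was 25 nt in the heterozygote and 26 nt in the mutant library.

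**Figure D1:**
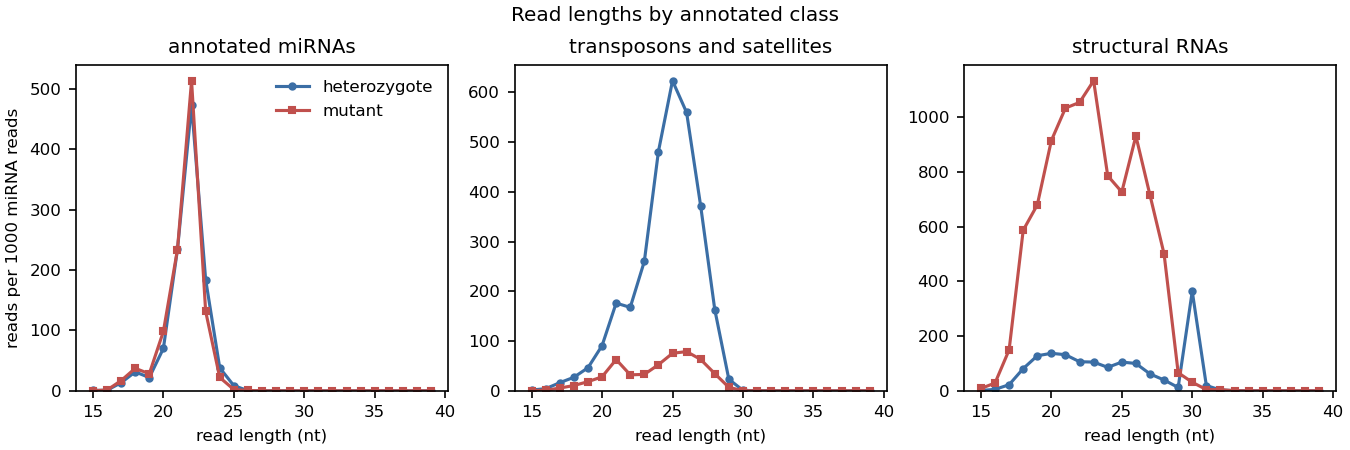
Reads per 1000 miRNA reads (vertical axes) against read length in nt (horizontal axes) for annotated miRNAs, for transposons with satellites, and for structural RNAs, with 1 line per library. The transposon and satellite curve of the mutant library lies far below that of the heterozygote, and its structural RNA curve lies above at most lengths, with the clearest exception at 30 nt.

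A uridine at the 5′ end is the usual mark of primary piRNAs. It was found on 71.7% of piRNA-size reads in the heterozygote library (71.7 to 71.8) and 67.4% in the mutant library (67.2 to 67.5), a difference of -4.36 percentage points. Transposon reads alone went the other way, from 72.0% to 76.5%, an alternative chosen after seeing the data. Single families went either way, with HeT-A from 63.3% to 42.5% and gypsy from 73.6% to 79.6%. Soma list families gave 63724 of 1018578 transposon reads in the heterozygote and 37560 of 205739 in the mutant library. Sense and antisense gene reads together went from 66.5% to 45.2%. They were 79632 of 1235224 and 80460 of 318938 piRNA-size reads. Changes in the mix of sources therefore enter the U shares of all piRNA-size and of transposon reads. Adenine at the tenth base, a mark of ping-pong partners, stood at 32.7% and 27.2% of all piRNA-size reads.

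The dual-strand clusters, sources of germline piRNAs read from both strands, had far fewer reads in the mutant library. Together they had a fold of 0.0566 (0.0553 to 0.0579). Cluster 42AB on 2R, with reads up to position 2382074, went from 179155 to 4061 reads per 1000000 miRNA reads, which is 44.1-fold lower. It was 68.0-fold lower for sequences at a single covered place and 21.5-fold lower for unannotated sequences, settings chosen after seeing the data. Cluster 38C-1 (dm3, 2L 20104428 to 20116379) went from 5096 to 15.05, a fold of 0.00295 (0.00135 to 0.00562). Cluster 80F (3L 23281076 to 23311513) went from 9532 to 43.5, a fold of 0.00456 (0.00298 to 0.00669). The intervals of 38C-1 and 80F are the least certain of those used.

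Cluster 38C-2 (2L 20148279 to 20226440) stood apart from the other dual-strand clusters with a fold of 0.241 (0.234 to 0.249). Its plus strand had a fold of 0.287 and its minus strand 0.0443. Of its reads, 9158 in the heterozygote and 5137 in the mutant library were annotated as the retrotransposon gtwin. Without gtwin sequences, an alternative chosen after seeing the data, its fold was 0.0226 and that of the dual-strand clusters together 0.0214. In 42AB both strands were lower, with folds of 0.0131 for the plus and 0.0284 for the minus strand.

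The uni-strand clusters differed much less between the libraries. Flamenco (X 21503143 to 21683347), the main piRNA source of follicle cells, had 30127 and 13403 reads per 1000000 miRNA reads, a fold of 0.445 (0.433 to 0.458). Cluster 20A (X 21392228 to 21429677), active in germ cells, had a fold of 0.455 (0.446 to 0.465). Plus-strand reads made up 96.1% and 95.6% of flamenco and 99.9% and 100% of 20A. Together the uni-strand clusters had a fold of 0.452 (0.444 to 0.459) per miRNA read and 0.245 per deposited read. Per flamenco read the dual-strand clusters had a fold of 0.127. The follicle cell miRNAs were 1.78-fold lower in the mutant library, and flamenco reads per read of these miRNAs had a fold of 0.792.

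**Figure D2:**
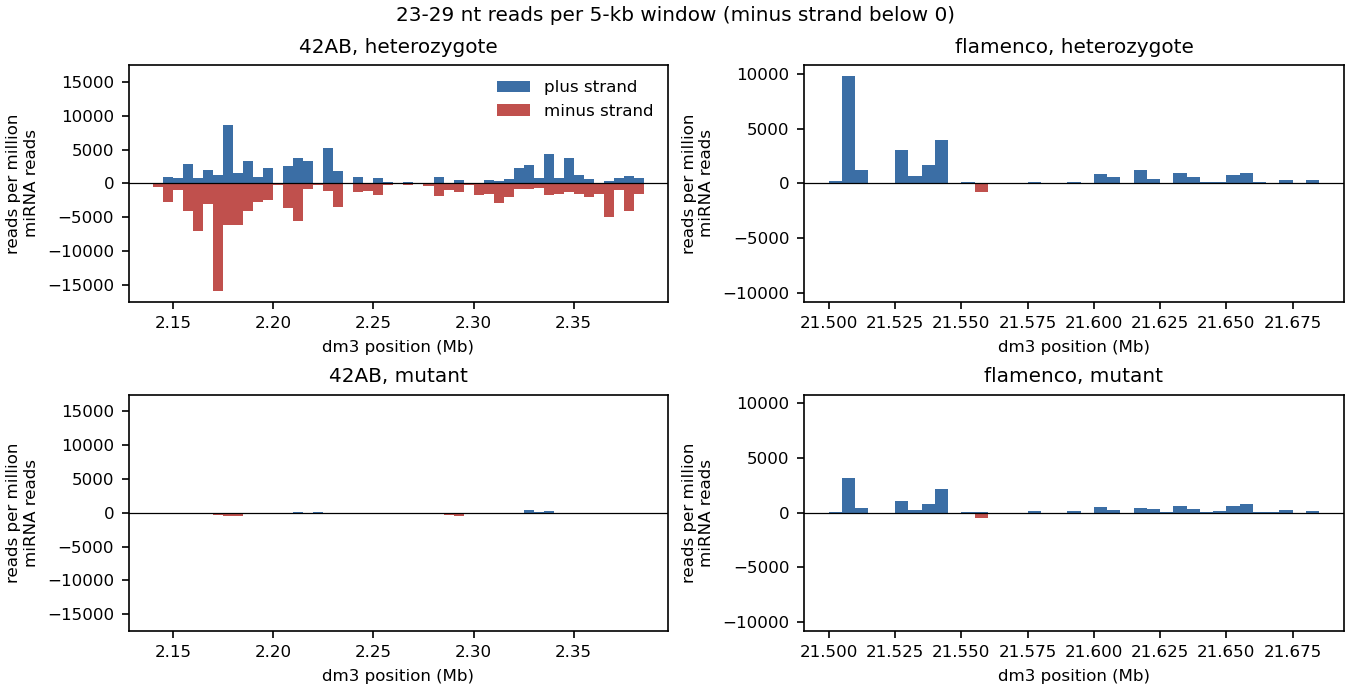
Reads of 23 to 29 nt per 1000000 miRNA reads (vertical axes, minus strand below 0) in 5-kb windows along 42AB and flamenco (horizontal axes, dm3 position in Mb), heterozygote above and mutant below on the same scale. 42AB is covered on both strands in the heterozygote and nearly empty in the mutant library, with folds of 0.0131 and 0.0284 by strand, while flamenco has a fold of 0.445.

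Of 92 transposon families with at least 1000 reads, 85 were at least 2-fold lower in the mutant library and 0 at least 2-fold higher. At least 10-fold lower were 54. By the class in the deposited annotation, the LINE elements had the lowest median fold, 0.0231 over 32 families, followed by DNA transposons at 0.0549 over 10 and LTR elements at 0.239 over 50. The lowest folds were those of NOF at 0.00239 (0.000959 to 0.00493), GYPSY8 at 0.00267, REHAVKUS-1_DY at 0.00272, Circe at 0.00302 and the G-element at 0.00303. TRANSIB2 at 0.00332, INVADER6 at 0.00335 and BS3 at 0.00365 came next. The median over families was -3.62 on the log2 scale per miRNA read, -4.50 per deposited read and -2.45 per flamenco read, and 92 and 66 families were at least 2-fold lower on the last 2 scales.

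The germline list held elements that are active in germ cells, and 25 of its 26 families were at least 2-fold lower per miRNA read, 26 per deposited read and 21 per flamenco read. Its median log2 fold was -4.27. This lay at percentile 20.6 of random lists, among families that were mostly lower themselves. Beside Circe and the G-element, Rt1a at 0.00391, BS at 0.00716 and Rt1b at 0.0102 had the lowest folds. The telomeric elements HeT-A, TART, TART-B and TAHRE stood at 0.0546, 0.0375, 0.0825 and 0.0182. The highest were copia at 0.584, Transpac at 0.362, rover at 0.296, roo at 0.253 and diver at 0.243.

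The soma list held gypsy-type elements taken to be controlled mainly, but not only, in follicle cells. The number of its 9 families at least 2-fold lower depended on the scale, with 4 per miRNA read, 9 per deposited read and 1 per flamenco read. Its median log2 fold was -0.97, at percentile 99.95 of random lists. The lowest were gypsy2 at 0.206, gypsy at 0.249, gypsy3 at 0.250, gtwin at 0.366 and Idefix at 0.511. The highest were gypsy10 at 0.824 (0.794 to 0.856), Tabor at 0.693, ZAM at 0.655 and gypsy5 at 0.619. Per flamenco read these 4 lay above 1, at 1.85, 1.56, 1.47 and 1.39. The germline median minus the soma median was -3.30 (-3.42 to -3.19) on the log2 scale, a difference that a common scale factor cannot change. Every family of the soma and intermediate lists is an LTR element, while the germline list also holds LINE and DNA elements. The LTR elements of the germline list ranged from 0.0141 (invader1) to 0.584 (copia). The middle one of these, Burdock, stood at 0.162, against a median of 0.511 for the soma list. Within LTR elements the gap between the lists was thus smaller than over the whole lists, in the same direction. The random lists were not matched on class, so list and class cannot be fully told apart.

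Of the 11 families of the intermediate list, found in both germ and follicle cells, 10 were at least 2-fold lower per miRNA read, 11 per deposited read and 4 per flamenco read. Its median log2 fold was -1.50, at percentile 99.6. The lowest were mdg3 at 0.0933, accord at 0.0989, DM176 at 0.133, DM297 at 0.212 (names as deposited) and Stalker4 at 0.284. The highest were blood at 0.600, mdg1 at 0.497, Stalker2 at 0.456, Quasimodo at 0.409 and DM412 at 0.405. Among all families the 8 highest folds were those of gypsy10, Tabor, ZAM, gypsy5, blood, copia, Idefix and mdg1, and per flamenco read all 8 exceeded 1.

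**Figure D3:**
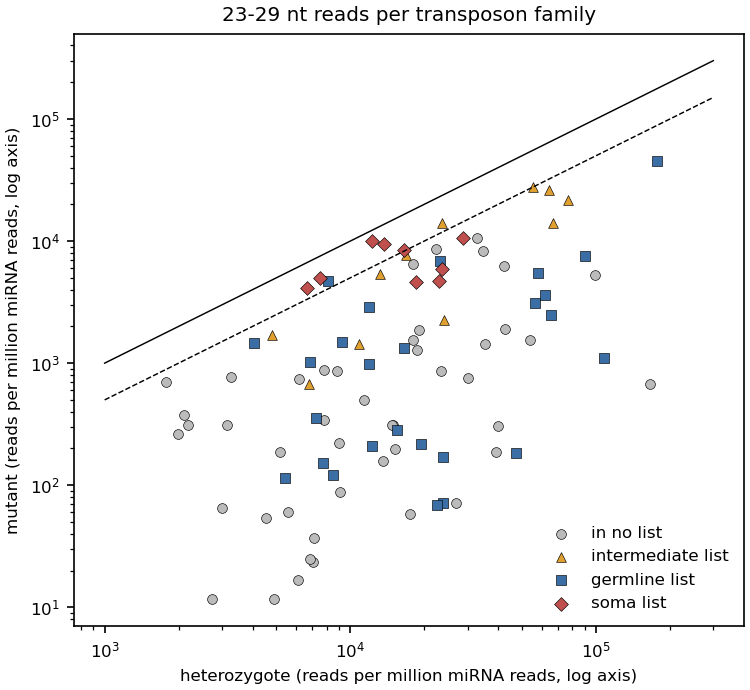
Reads of 23 to 29 nt per 1000000 miRNA reads in the heterozygote (horizontal, log axis) and mutant library (vertical, log axis), with 1 point per transposon family of at least 1000 reads. The solid line marks equal values and the dashed line a fold of 0.5, below which 25 of 26 germline families and 4 of 9 soma families lie on this scale, against 21 and 1 per flamenco read and all of both lists per deposited read.

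Ping-pong pairs, in which 2 piRNAs from opposite strands overlap by 10 nt at their 5′ ends, were prominent in the heterozygote library and much scarcer in the mutant library. Their share of overlaps was 27.7% there (z-score 15.3) and 2.90% in the mutant library (z-score -0.51). In the dual-strand clusters the share was 37.2% in the heterozygote library. It was 0% in the mutant library, on only 37 pairs of distinct sequences, too few for a close limit on the share. Counted by reads, 17.99% of piRNA-size reads in these clusters had a partner at 10 nt in the heterozygote library. The mutant library had 0 such reads, which allows up to 0.0384% of its reads there but sets no limit on the share of overlaps. For the germline list the share of overlaps was 45.3% and 8.03%, for the intermediate list 24.7% and 9.49%, and for the soma list 15.9% and 4.01%. The mutant z-scores of these lists were 2.88, 2.99 and -0.17, and for distinct sequences 1.78, 2.82 and -0.78. In the uni-strand clusters it was 3.31% and 3.39%, with z-scores below 0 in both libraries. Reads with a partner at 10 nt made up 10.4% (10.3 to 10.4) and 1.62% (1.57 to 1.66) of piRNA-size reads. At the neighbouring overlaps of 9 and 11 nt both values were 4.21% in the heterozygote, and 1.63% and 1.64% in the mutant library, where 10 nt showed no excess. With each distinct sequence counted once the shares were 10.5% and 4.80%.

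**Figure D4:**
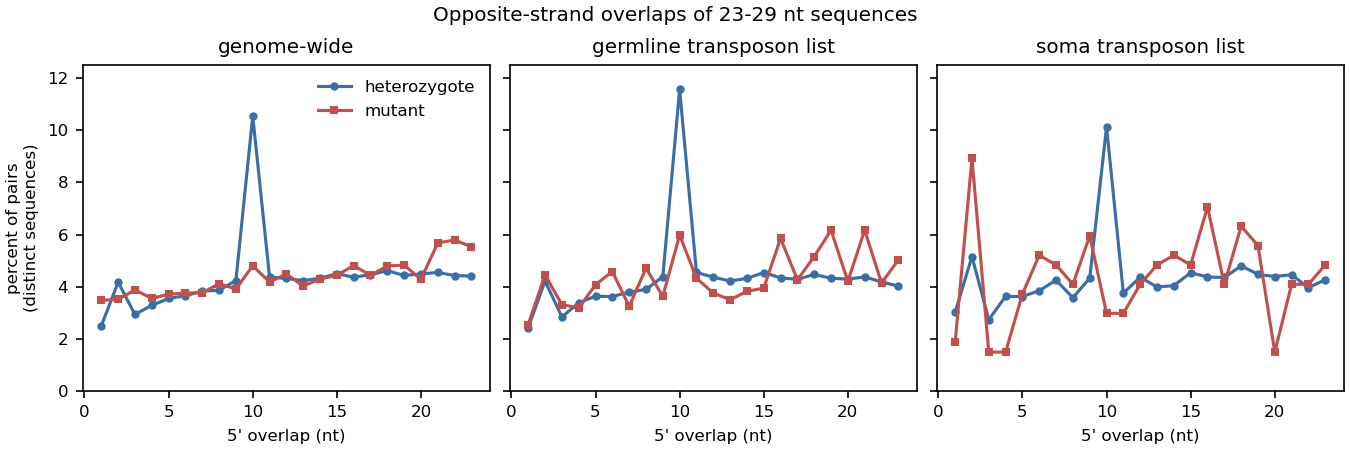
Percent of opposite-strand pairs of distinct sequences (vertical axis) by the length of their 5′ overlap in nt (horizontal axis), genome-wide and for the germline and soma lists, with 1 line per library. The heterozygote line peaks at 10 nt in all 3 panels, at 10.5% genome-wide, where the mutant line stands at 4.80%.

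Of 56 miRNAs with at least 1000 reads, 15 were at least 2-fold higher and 12 at least 2-fold lower in the mutant library as shares of miRNA reads. Per deposited read this split was 10 and 28, and with scaling by the median ratio 15 and 7. The 10 most abundant were mir-14 (10.9% and 19.5% of miRNA reads), bantam (9.77% and 5.80%), mir-276a (3.98% and 8.27%), mir-305 (3.78% and 4.81%), mir-184 (4.90% and 3.18%), mir-310 (4.76% and 2.88%), mir-34 (1.93% and 5.64%), mir-312 (3.64% and 3.72%), mir-989 (4.77% and 1.91%) and mir-995 (4.51% and 1.38%). Of these, mir-14, mir-305 and mir-312 were higher in the mutant library per miRNA read but lower per deposited read, at 0.974, 0.691 and 0.555. Only mir-276a and mir-34 were higher on both scales, at 1.13 and 1.58 per deposited read, and the rest were lower on both.

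The highest miRNA folds belonged to mir-286 at 82.6 (49.1 to 151), mir-984 at 36.4, mir-6-1 at 31.6 and mir-983-1 at 27.6. They were followed by mir-986 at 5.59, mir-316 at 5.46, mir-31a at 5.23 and mir-1 at 4.23. The lowest folds were mir-995 at 0.306, mir-308 at 0.337, mir-92b at 0.375, mir-79 at 0.376, mir-989 at 0.399, mir-92a at 0.416, mir-9c at 0.429 and mir-mirtron1 at 0.460.

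Markers of other cell types differed as well. The follicle cell miRNAs mir-318, mir-994 and mir-989 had folds of 0.831, 0.510 and 0.399, and 0.562 together. The maternal and germline list of mir-310, mir-311, mir-312, mir-313, mir-184, mir-9c, mir-306 and mir-79 had 0.690, with 1 of 8 above 1. The muscle miRNA mir-1 stood at 4.23 and mir-133 at 2 and 1 reads. The adult soma list had 1.35, with let-7 at 1.055, mir-100 at 1.46 and mir-125 at 2.46. The carcass list had 1.49, with mir-276a at 2.08, mir-276b at 1.64, mir-281-1 at 1.51, mir-281-2-3p at 1.20, mir-7 at 0.735 and mir-8 at 0.701, while mir-124 had 0 and 1 reads. Most reads of the carcass list were mir-276a, 16877 of 30956 in the heterozygote and 49450 of 65331 in the mutant library. The fold of that list therefore mainly reflects this 1 miRNA. Per deposited read the adult soma and carcass lists lay below 1.

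**Figure D5:**
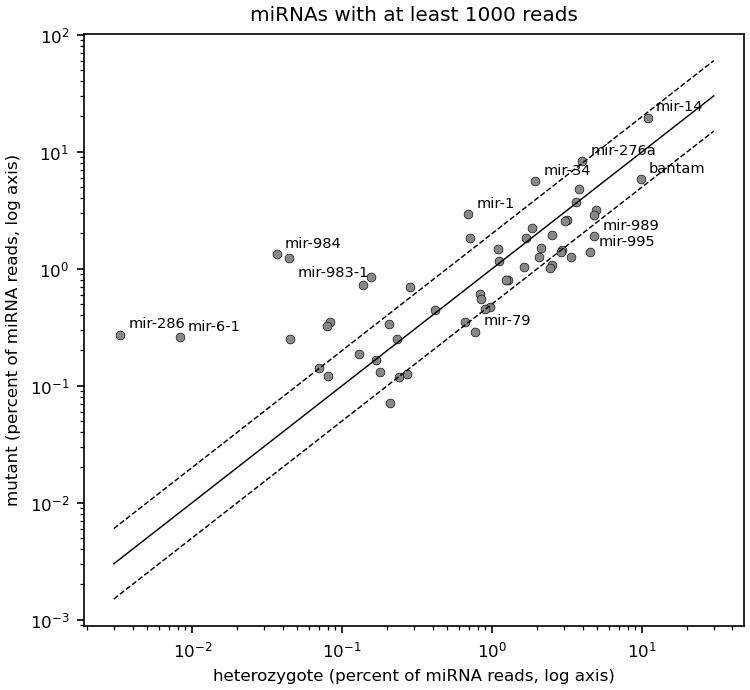
Percent of miRNA reads in the heterozygote (horizontal, log axis) and mutant library (vertical, log axis), with 1 point per miRNA of at least 1000 reads. The solid line marks equal shares and the dashed lines 2-fold differences, and mir-286, mir-6-1, mir-984 and mir-983-1 lie far above at folds of 27.6 to 82.6.

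Genes with sense reads of piRNA size showed no common direction. Over the 20 protein-coding genes with most reads the median fold was 1.02 (0.916 to 1.11), with 7 at least 2-fold lower and 7 at least 2-fold higher. It was 0.553 per deposited read and 2.29 per flamenco read. The heat shock gene Hsp70Aa went from 1313 to 19 reads, a fold of 0.0103 (0.00615 to 0.0161). Nipped-A had a fold of 0.170, anne 0.251 and CkIIalpha 0.108. FASN2, a fatty acid synthase gene, went from 85 to 5041 reads, a fold of 42.01 (33.9 to 52.7), and CG31191 had 32.1. Only 12.0% and 6.11% of the mutant reads of FASN2 and CG31191 began with uridine.

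Among the other genes with most reads, the translation factor gene eEF1alpha1 stood at 3.20 and Smr at 4.28. The histone genes His2B:CG17949 and His2A:CG33844, members of a repeated array whose copies share reads, stood at 0.889 and 0.955. Traffic jam (tj), a follicle cell source of piRNAs, had 2 and 0 reads annotated to it, too few for a fold. For brat the fold was 1.33 (0.893 to 2.001) and for Ras85D 0.974 (0.357 to 2.79), both within counting error of 1. For pcm it was 3.36 (1.12 to 13.6) and for jing 0.216 (0.109 to 0.399).

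Hairpin-derived siRNAs of 21 nt had a fold of 1.59 (1.48 to 1.71) per miRNA read and 0.863 per deposited read. The locus annotated as si1 had 1.09 (0.985 to 1.20) and si2 had 2.26 (2.04 to 2.50). Transposon reads of 21 nt had a fold of 0.364 (0.360 to 0.369). Of the germline list, 21-nt reads had 0.373 and piRNA-size reads 0.101. Of the soma list they had 0.436 and 0.418. Reads of 21 nt made up 5.89% of transposon reads in the heterozygote and 12.5% in the mutant library.

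Outside the fixed clusters, the 5-kb windows with the largest losses included telomeric repeats, chromosome 4 and heterochromatin. The window 3R 27895001 to 27900000, mostly of the repeat HETRP, went from 23199 to 36.8 reads per 1000000 miRNA reads. On chromosome 4 the windows starting at 1330001 and 1325001 (TART) and 1285001 (HeT-A) had folds of 0.0341, 0.0229 and 0.0580. The others were 3LHet 995001 without annotation at 0.174, 2L 22660001 (Max-element) at 0.0327, 3L 23105001 (R1) at 0.00141, 3L 21240001 (DM412) at 0.443, 2R 21145001 (HETRP) at 0.00241 and 2LHet 260001 (roo) at 0.246. The Su(Ste) repeats went from 12770 to 1525, a fold of 0.119 (0.111 to 0.128).

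The largest gain was in the window 2L 3045001 to 3050000, which holds the FASN2 reads, from 210.1 to 8457 reads per 1000000 miRNA reads. The windows 2RHet 360001 (blood) and 2R 7780001 (eEF1alpha1) had folds of 2.52 and 3.42. The window 2R 15610001 without annotation had 9.67 and 2L 17820001 (copia) had 1.92.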

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

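The piRNA-size ratio per miRNA read, the germline to soma difference and the fold per flamenco read were planned before the data were examined. Their use against the explanations below, and both tests of 38C-2, were chosen only after the results were seen. Antisense reads on the eye colour gene white appeared in both libraries, 4423 in the heterozygote and 18956 in the mutant, outside the main comparisons and far above the limit of 3 counts. The commonest was the 22-nt sequence TTTGCTGAGCGAAAGCTCCTGG (dm3, X 2686481 to 2686502), with 2944 and 11767 reads. The headings of both count columns carry the letters shW, and that of the heterozygote the letters wt, which the labels do not explain. Reads outside the labelled 19 to 29 nt made up 10.41% of the heterozygote and 8.25% of the mutant library. Of these 277226 and 571736 reads, 152578 and 11449 were 2S rRNA of 30 nt. The cause of this difference was not tested.

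The loss of piRNA-size reads in the mutant library came with many more fragments of structural RNAs. As a share of all reads, dilution by such fragments lowers every source of piRNAs, and the miRNAs too, by 1 factor. That factor cancels per miRNA read, where piRNA-size reads still had a ratio of 0.183. The germline list also lay below the soma list by a median log2 difference of -3.302, which 1 common factor cannot produce. Dilution therefore cannot account for the loss per miRNA read or for the difference between the lists. The fold of the dual-strand clusters per flamenco read, 0.1271, is consistent with an effect of the cuff genotype. With 1 library per genotype, this cannot be told apart from another difference between the libraries.

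Cluster 38C-2 kept more of its reads than 42AB, 38C-1 and 80F. Without gtwin sequences its fold fell to 0.02257, close to that of 42AB, so the reads it kept were mostly gtwin. They may come from gtwin copies elsewhere that share the sequence. Sequences at a single place in the covered genome kept a fold of 0.2603, but a copy is seen there only if another sequence was placed on it, so this origin stays open.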

How the results depend on the processing

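No paired analysis was possible because there was 1 library per genotype and no test. Settings on the median miRNA ratio (except for the miRNA counts), a single covered place, annotation, gtwin, U starts, and thinned distinct sequences were chosen after seeing the data. Per deposited read the folds were 0.0992 for piRNA-size reads, 0.03068 for dual-strand and 0.2449 for uni-strand clusters, 0.5531 for genic reads and 0.8633 for hairpin siRNAs, which turned the last. Per flamenco read they were 0.1271 for dual-strand clusters and 2.292 for genic reads. With the median miRNA ratio they were 0.203, 0.06278, 0.5012, 1.132 and 1.767 for piRNA-size, dual-strand, uni-strand, genic and hairpin reads. With 24 to 28 nt, piRNA-size reads had 0.1766, uni-strand clusters 0.4347 and the U share a difference of -3.239 points. For transposons only that difference was 4.438, reversed in sign. Transposons and satellites had a fold of 0.1388. At a single covered place, dual-strand clusters had 0.05855, the germline to soma difference was -3.689 and the ping-pong difference -16.44 points. Unannotated sequences gave 0.0454 for dual-strand and 0.3924 for uni-strand clusters, and leaving out gtwin gave 0.02136 for dual-strand clusters. The ping-pong difference, -24.81 points, was -5.748 for distinct sequences, -26.08 at equal numbers of reads and -10.62 for both together. With a minimum of 100 reads, 47 miRNAs differed at least 2-fold, more being counted (86 against 56). Genic reads that start with U had 0.876, and hairpin reads of 20 to 22 nt 2.171. Apart from the added counting of more miRNAs, the cause was not tested. Of 49 alternatives, another 16 stayed within the interval or within 1.5 times the count. A further 4 could not move the germline to soma difference, since they were a common scale factor or added no list member. Division by the number of places, 1 mismatch and antisense against both strands were not run, since the counts carry 1 place and no transposon orientation.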

Other observations

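Every test in this part was chosen only after the values were seen. The miRNAs of the mir-309 cluster, which early embryos express, stood at 69 reads in the heterozygote and 5447 in the mutant library, a fold of 55.9 (44.1 to 72.0). The 18 testis-enriched miRNAs together had 469 and 16754 reads, a fold of 25.3 (23.1 to 27.8). Of the mutant reads, mir-984 gave 7973 and mir-983-1 gave 7320, and these 2 alone passed the minimum of 1000 reads. The subtelomeric entry named xtas went from 3365 to 34 piRNA-size reads, a fold of 0.00716 (0.00495 to 0.0100). Mitochondrial reads of all lengths had a fold of 2.26 (2.20 to 2.33).

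Fragments of messenger RNAs give another view of the tissue. Per 1000000 sense gene reads, a list of 13 egg chamber genes had 1943 (1648 to 2276) in the heterozygote and 1113 (946.6 to 1300) in the mutant library. A list of 14 germline genes had 6375 and 9791, and a list of 14 muscle genes had 1549 (1287 to 1850) and 1267 (1089 to 1465).

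RNA of testis or of embryos may have added the mir-309 cluster and testis-enriched miRNAs to the mutant library. None of 16 testis genes had a sense read in either library, which allows up to 20.99 per 1000000 sense gene reads in the mutant. Reads of piRNA size placed on Y heterochromatin were lower in the mutant library, at 354 and 139 reads, a fold of 0.278 (0.227 to 0.339). The Su(Ste) repeats were lower too, at 0.119. Both were already present in the heterozygote library, so a lower total sets no limit on added testis RNA. Fragments of 18 early zygotic genes, 11 of them detected in these ovary libraries, had a ratio of shares of 1.409, on 52 and 133 reads. Per 1000000 sense gene reads the values were 660.4 (493.2 to 865.9) and 930.8 (779.4 to 1103), with overlapping intervals. The muscle list was lower in the mutant library, also with overlapping intervals, and such overlap does not test a ratio. With intervals apart, the egg chamber list was lower and the germline gene list higher in the mutant library. A higher share was thus not particular to the zygotic list. The share of foreign RNA that these miRNAs would need is not known, so neither source can be ruled out, and neither reads carried over from another library nor an effect of the genotype was tested.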
